A study of Oryza sativa Indica Group with 23 samples.

How the data were processed

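The series holds 23 Affymetrix rice arrays of root RNA from 4 genotypes, FL478, IR29, IR63731 and Pokkali, in 2 treatments, control and salt. Per the labels' protocols, RNA was extracted with TRIzol and a spin column with DNase treatment, and biotin-labelled cRNA was hybridised. The deposited values are on the log2 scale, 1 column per array, and were made with RMA per the submitters' processing notes. The version of RMA, its software and the probe set definition are not given in the sources used here. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

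Of 57381 probe sets, 123 AFFX controls and 64 reporter probe sets were left out and 57194 rice probe sets were tested. In the array annotation 22436 probe sets had 1 gene, 95 had several and 34663 had none listed. All 17905 genes with a probe set of their own were found in the RefSeq gene table, which was used for names and for which genes neighbour each other, and 2436 had a name besides a locus or clone identifier. A gene was represented by its probe set with the highest mean. Of 243 genes picked by the rule for named genes, 54 had several probe sets, and in 40 of these all probe sets had one direction in the mean of 4 genotypes.

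Values were fitted with limma 3.58.1 in R 4.3.3, as 8 group means over all arrays with 1 estimate of the spread, because groups hold 2 or 3 arrays. Tests were two-sided with Benjamini-Hochberg adjustment over probe sets, and an adjusted p under 0.05 counts as passing. The comparisons were salt against control in each genotype, the equally weighted mean of these 4, the differences of the salt effects between genotypes, and the genotypes' control plants. These comparisons, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 8 largest changes each way in the mean of 4 genotypes, the 6 largest each way in each genotype, 2 members each way of each gene list, the 5 largest each way between control plants, and genes known from earlier work on salt. Further list members were chosen after their values were seen. Of 14 genes known from earlier work, 8 were found by name, and the other 6 were not analysed here.

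Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. A list counts as called by camera at the preset correlation. The tests can differ: in FL478 fry put beta-glucosidase and auxin genes higher (fry adjusted p = 0.0326 and 0.0334), and camera called neither. There were 49 lists, 28 planned before the data were examined and matched to the annotation's names, and 21 added after the annotation's names were seen and before any comparison was computed. Lists of at least 5 genes were tested, which left 47. Class III peroxidases (4 genes, 1 lower) and root hair genes (2 genes, 0 passing) were too short to test.

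Replicate numbers were checked for pairing by the correlation of deviations from group means between control and salt arrays of the same number. Pairs over a minimum of 0.1 throughout were found in FL478 (0.421, 0.197 and 0.287) and IR63731 (0.142, 0.296 and 0.252), so the fit with the number as a block is given beside their results. The labels do not say what a number stands for.

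Alternatives were the replicate block, a filter at the median probe set, eBayes with trend and robust, array weights, quantile normalization again, leaving out _s_at and _x_at probe sets, fits with only the arrays compared, and leaving out each array in turn. The fit without FL478 salt replicate 2, FL478 control replicate 3 and IR29 control replicate 1 was added after seeing the data. So were the fits of the mean of 4 genotypes with a covariate per array, either the level of the clock genes PCL1, PRR1 and GI less that of CCA1, or the 3 prime minus 5 prime value averaged over the control probe sets of actin, Gapdh, cyclophilin and ubiquitin. Positions between genotypes used probe sets that set 1 genotype apart from the others by at least 2 log2 units. The array placed and the 3 arrays between genotypes were left out of the genotype means and of the choice of these probe sets. The position of FL478 between IR29 and Pokkali used probe sets with an adjusted p under 0.01 and at least 2 log2 units between these, and neighbours were compared with 10000 shuffles.

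The code was tested on simulated data with 200 changed probe sets. For FL478 salt against control, 27 of 67 changes of 1.5-fold, 59 of 67 of 2-fold and 63 of 66 of 4-fold were recovered, with 5 unchanged probe sets called. For the mean of 4 genotypes, 59 of 67, 66 of 67 and 65 of 66 were recovered, with 12 unchanged probe sets called. The simulated noise was independent between probe sets and arrays, with no shared effect of replicate number and no array between genotypes. Recovery and false calls in the real arrays may therefore differ. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Gene lists for proton pumps and cytosolic ribosomal proteins matched no name and were not analysed here.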

Results

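Root RNA of 4 rice genotypes was measured on 23 Affymetrix rice arrays, 11 from control plants and 12 from plants under salt. FL478, IR63731 and Pokkali had 3 arrays in each treatment, and IR29 had 2 control arrays and 3 salt arrays. IR29 control has no replicate number 3. FL478 is a salt-tolerant recombinant inbred line from a cross of the salt-sensitive variety IR29 with the tolerant landrace Pokkali, and IR63731 is a further tolerant line. Sodium chloride and calcium chloride were added to the nutrient solution from day 22 in 2 steps over 3 days, to 7.4 dS per m, and all roots were taken on day 30. The comparisons ask which genes roots of each genotype change under salt, whether tolerant and sensitive genotypes change them to different extents, and how the genotypes differ without salt. Array medians lay between 4.31 and 4.41 on the log2 scale, and the number of arrays limits the precision of every value given here.

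The first 3 principal components held 22.4%, 15.8% and 14.1% of the variance between arrays and had r2 of 0.989, 0.851 and 0.819 with genotype. The fourth, with 11.2% of the variance, had an r2 of 0.556 with treatment and 0.237 with replicate number, and the fifth, with 6.86%, one of 0.507 with replicate number. Correlations across probe sets between pairs of arrays ran from 0.969 to 0.994, and 21 of the 23 arrays were closest to another array of their own genotype. At 85 to 148 probe sets private to a genotype, 20 arrays lay between 0.92 and 1.04 of the way to their own genotype and between -0.03 and 0.05 of the way to the others. The other 3 arrays lay between 2 genotypes. FL478 salt replicate 2 stood at 0.39 for FL478 and 0.60 for IR63731, IR29 control replicate 1 at 0.55 for IR29 and 0.48 for IR63731, and FL478 control replicate 3 at 0.81 for FL478 and 0.22 for IR63731. The genotype means and private probe sets were set without these 3 arrays and without the array placed. With all other arrays as reference, the 3 stood at 0.40 and 0.58, 0.54 and 0.48, and 0.87 and 0.18, in the same order. The other 20 then ran from 0.96 to 1.18 for their own genotype and from -0.16 to 0.03 for the others. Counts of probe sets are therefore also given without these 3 arrays, an alternative chosen after seeing the data.

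**Figure D1:**
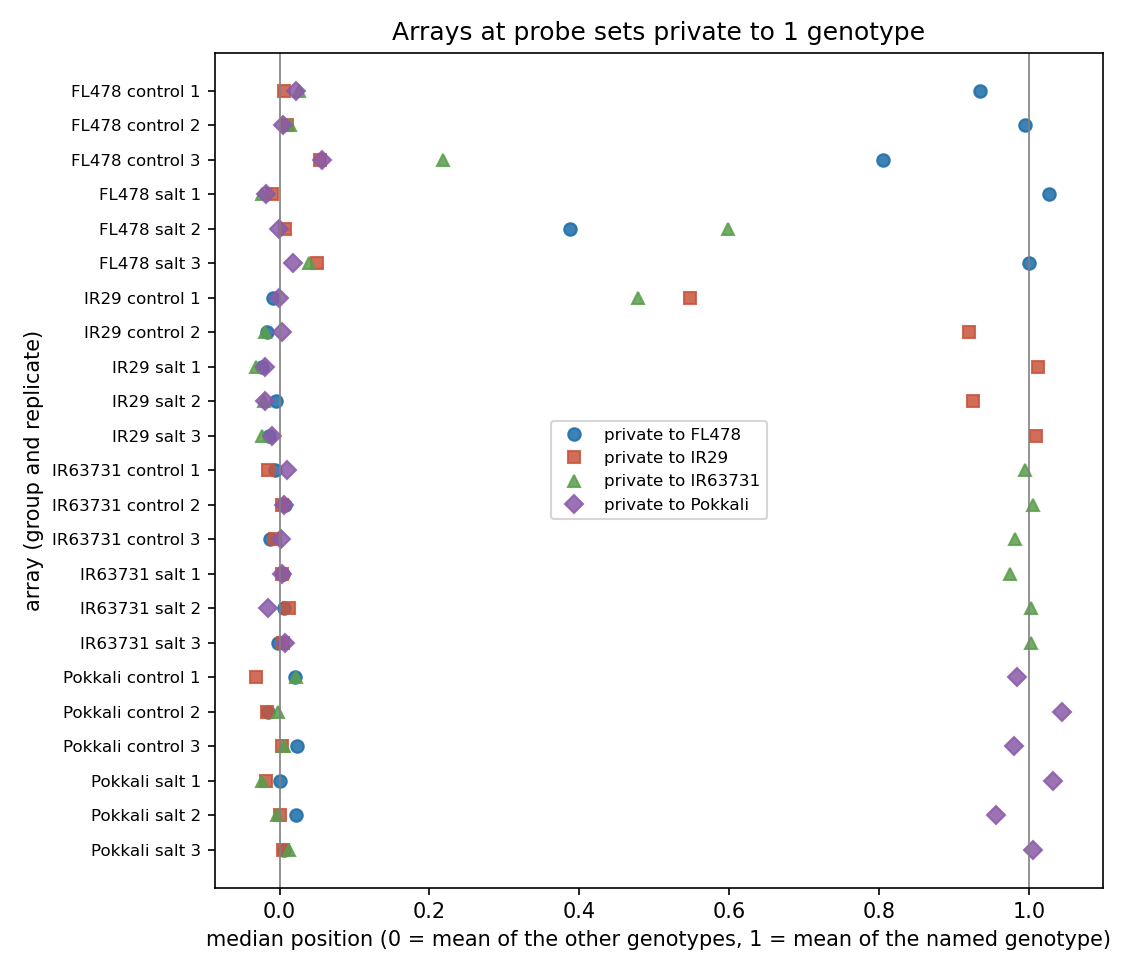
Each point is the median position of 1 array at the probe sets private to 1 genotype, with 0 at the mean of the other genotypes and 1 at the mean of the genotype named in the legend. The array placed and the arrays lying between genotypes were left out of these means and of the choice of probe sets. FL478 salt replicate 2, IR29 control replicate 1 and FL478 control replicate 3 lie between IR63731 and the genotype of their label, and the other 20 arrays lie between 0.92 and 1.04 for their own genotype.

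Arrays with the same replicate number deviated together across genotypes. Pairs of arrays with the same number had a mean correlation of deviations from their group means of 0.199, against -0.0987 for other pairs (permutation p = 3e-05), and 21 of 23 arrays were nearest their own number. Of 7 genes of the circadian clock, 4 differed between numbers 2 and 3. PRR73, PRR37 and PRR95 did not pass there (adjusted p = 0.166, 0.249 and 0.538). From number 2 to number 3, the dusk gene PCL1 had a log2 change of -4.39 (SE 0.36, adjusted p = 3.04e-06) and GI one of -1.72, and the dawn gene CCA1 had one of 2.06. In the mean of 4 genotypes none of the 7 clock genes measured passed for salt without a block, with PCL1 at 1.35 (SE 0.92) and CCA1 at -0.91 (SE 0.44). With replicate number as a block CCA1, PRR1 and PCL1 passed (adjusted p = 0.000109, 0.00138 and 0.00143).

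**Figure D2:**
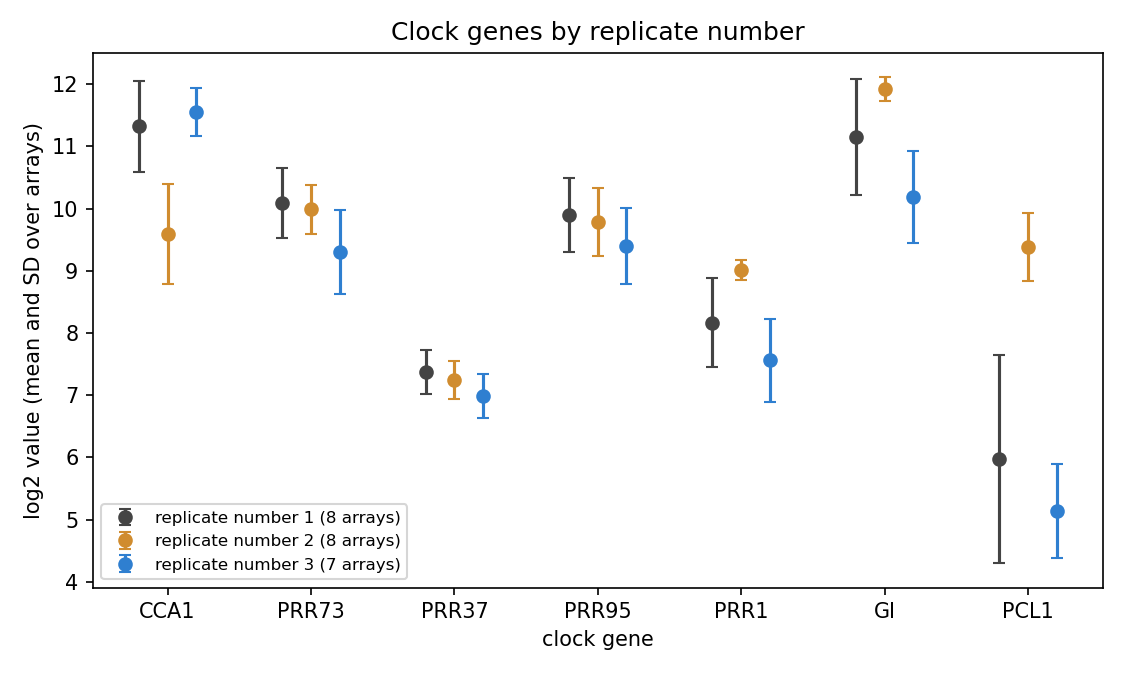
Each point is the mean log2 value of 1 clock gene over the arrays of 1 replicate number (8, 8 and 7 arrays), and bars are SD over arrays. PCL1, GI and PRR1 lie highest and CCA1 lowest in number 2.

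Averaged over the 4 genotypes, the proline synthesis gene P5CS2 and the expansin genes EXP31 and EXPB18 were higher under salt, and genes of sugar transport and sucrose metabolism were lower as a list. BURP10, a BURP-domain protein gene, rose most among named genes, by a log2 change of 2.26 (SE 0.25, 4.80-fold, adjusted p = 2.19e-05). P5CS2, which encodes delta-1-pyrroline-5-carboxylate synthetase of proline synthesis, rose by 1.06 (SE 0.12, 2.09-fold, adjusted p = 2.19e-05). The expansin genes EXP31 and EXPB18 rose by 1.17 and 1.03, and SMR1, SS1, the beta-glucosidase gene BGLU27 and the ammonium transporter gene AMT3-2 by 1.22, 1.03, 1.02 and 0.98. The list of 30 cell wall loosening genes, to which the expansins belong, was not called (camera adjusted p = 0.986): 3 rose and 3 fell, or 4 and 3 adjusted over the list alone. All 12 salt arrays lay above the control mean of their genotype for each of the 8 named genes that rose most, BURP10 to AMT3-2. Among named genes with all arrays the largest falls were those of CAO, which encodes chlorophyllide a oxygenase of chlorophyll b synthesis (-2.00, SE 0.46, adjusted p = 0.0101), and GLT2 (-1.89, SE 0.56, adjusted p = 0.0422). OsPM19L1 (-1.79), the BURP-domain gene BURP2 (-1.73), Pir7b (-1.62), HIRL2 (-1.41), the heat shock factor gene HSF05 (-1.31) and the auxin transporter gene PIN5A (-1.30) also fell. At least 10 of the 12 salt arrays lay below the control mean of their genotype for each of these 8 genes. Of these 16 genes, CAO, GLT2, PIN5A and AMT3-2 also differed between replicate numbers, by 2.29, -2.68, 0.81 and 0.74 from number 2 to number 3 (adjusted p up to 0.0147). With the level of 4 clock genes as a covariate, CAO stood at -1.16 and GLT2 at -2.78, and OsPM19L1 (-1.76), Pir7b (-1.67), BURP2 (-1.64) and HIRL2 (-1.47) then fell by more than CAO.

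**Figure D3:**
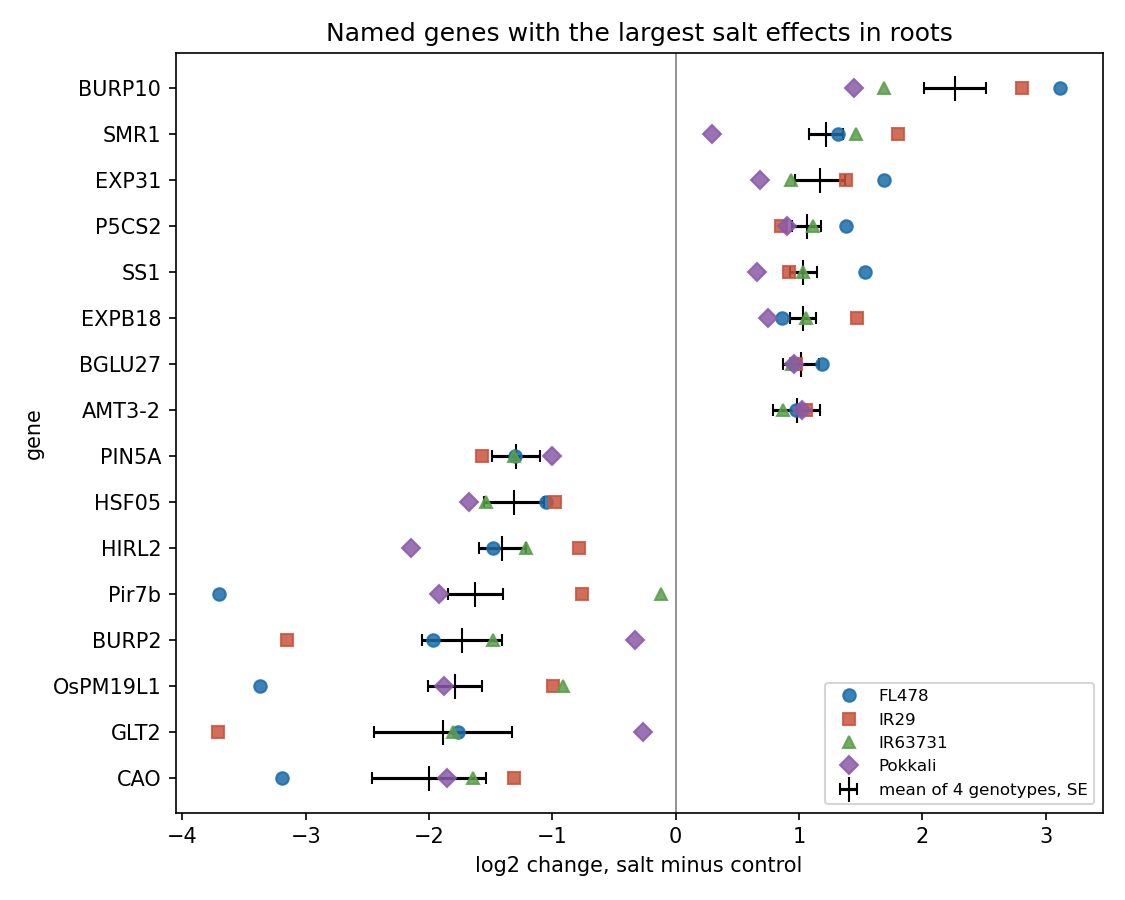
Each row is 1 gene named by rule for the mean of 4 genotypes, and the horizontal axis is its log2 change, salt minus control. Coloured points are the 4 genotypes and the black bar is their mean with its standard error. BURP10 lies highest at 2.26 and CAO lowest at -2.00, and GLT2 and Pir7b spread most between genotypes.

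In all, 2830 probe sets were higher and 1923 lower in salt in the mean of 4 genotypes, of 57194 tested with limma and an adjusted p under 0.05. Of these, 73 rose and 143 fell by over 2-fold. With replicate number as a block 4195 were higher and 2919 lower. Without the 3 arrays between genotypes 1652 were higher and 1051 lower, of which 1430 and 944 had been called with all arrays, and all 4753 kept their direction. Of the 16 named genes, CAO no longer passed in that fit (-1.49, adjusted p = 0.104). GLT2 no longer passed when any of 15 of the 23 arrays was left out, with adjusted p from 0.0546 to 0.098. The difference between 3 prime and 5 prime probe sets, a measure of RNA quality averaged over 4 control genes, was higher in salt by 0.0843 (two-sided permutation p = 0.0194). The 4 genes did not move alike. Actin (1.07 in salt, 0.89 in control) and Gapdh (1.21 and 1.05) were higher. Ubiquitin was little changed (-0.66 and -0.69) and cyclophilin slightly lower (1.14 and 1.16). With the average as a covariate, 1006 probe sets were higher and 801 lower, and 1763 of the 4753 (37.1%) were still called. CAO (-1.88, adjusted p = 0.0725) and GLT2 (-2.14, adjusted p = 0.0909) then did not pass, and the other 14 named genes did. Of the further genes named by rule for this mean and given here, SalT, NIA1, HXK4 and NAS3 did not pass with it (adjusted p = 0.0941, 0.0596, 0.143 and 0.163).

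Genes known from earlier work on salt in rice went different ways. RAB16A, a dehydrin gene, rose by 0.79 (SE 0.12, adjusted p = 0.000557). AKT1, an inward potassium channel gene, fell by 0.70 (adjusted p = 0.0016) and SalT, which encodes a mannose-binding lectin, fell by 0.54 (adjusted p = 0.00804). SalT did not pass without the 3 arrays between genotypes (adjusted p = 0.0585). HKT1;5, a sodium transporter gene of the root xylem parenchyma, had a log2 change of 1.03 (SE 0.35) that did not pass (adjusted p = 0.0789), with 10 of 12 salt arrays above their control mean. It passed without the 3 arrays between genotypes (1.55, adjusted p = 0.00521). In IR29 alone its change ran from -0.96 to 0.99 when 1 array was left out. In the mean HKT1;5 also passed with replicate number as a block (0.94, adjusted p = 0.0189) and with array weights (1.07, adjusted p = 0.0468). It did not pass with trend and robust, with quantile normalization again or with the 3 prime minus 5 prime covariate. It passed with the clock covariate (1.47, adjusted p = 0.00489) and without FL478 control replicate 3, IR29 control replicate 1 or IR29 salt replicate 2 alone (adjusted p = 0.0112, 0.045 and 0.0413). LEA3 (0.06), DHN1 (-0.27), P5CS1 (0.02) and NAC6 (-0.12) did not pass, with adjusted p from 0.299 to 0.919.

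Sugar transport and sucrose metabolism was the list with the smallest p among the 47 gene lists tested in the mean of 4 genotypes. Of its 41 genes, 10 fell and 1 rose, or 12 and 2 adjusted over the list alone, and the camera test put the list below the other genes (adjusted p = 0.000933). The call held with an estimated correlation (adjusted p = 0.00678 with an estimated correlation). The sugar transporter gene SWEET4 fell by 0.96, the hexokinase genes HXK6 and HXK2 by 0.69 and 0.45, the invertase gene CIN2 by 0.59 and the sucrose synthase gene SUS1 by 0.21. HXK4 rose by 0.23, and did not pass without any 1 of 8 arrays (adjusted p up to 0.103) or with the clock covariate (adjusted p = 0.0875). Iron uptake and storage was also called (adjusted p = 0.00637), with 4 of 25 genes lower, or 7 adjusted over the list alone, and none higher. That call was lost with an estimated correlation (adjusted p = 0.749 with an estimated correlation). The iron list was also called between replicate numbers, as higher in number 3 than in number 2 (adjusted p = 0.0107, and adjusted p = 0.77 with an estimated correlation), with a median of 0.159 against -0.112 for salt. The vacuolar iron transporter gene VIT1 fell by 0.49, the nicotianamine synthase gene NAS3 by 0.69 and the metal-chelate transporter gene YSL9 by 0.60. NAS3 did not pass without IR29 control replicate 1 (adjusted p = 0.0766) or with the clock covariate (adjusted p = 0.0835). Random regroupings of the arrays within genotypes gave a median of 3 lists called, against the 2 called here. Leaving out FL478 control replicate 2, IR29 control replicate 2, IR29 salt replicate 3, Pokkali control replicate 2 or Pokkali salt replicate 2 gave 5 lists each. Leaving out IR63731 control replicate 2, IR63731 salt replicate 1 or Pokkali control replicate 3 gave 4 each.

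In other groups some members passed each way, and the lists were not called by camera. Of 20 genes of nitrogen uptake and assimilation, 5 rose and 4 fell, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.601). The nitrate transporter genes NRT2.2 and NRT2.3 and the nitrate reductase gene NIA1 were among those that rose, by 0.80, 0.63 and 0.42. The glutamate dehydrogenase genes GDH1 and GDH2 and the cytosolic glutamine synthetase gene GLN1-2 fell by 0.58, 0.95 and 0.19. Of 14 osmolyte genes, P5CS2 rose and the trehalose-phosphate phosphatase genes TPP2, TPP9 and TPP10 fell, by 1.25, 0.82 and 0.32 (camera adjusted p = 0.0527). Of 26 zinc, copper and manganese transport genes, 3 rose and 7 fell, or 4 and 9 adjusted over the list alone, among them HMA5, a copper transporter gene that fell by 0.77, and ZIP3, which fell by 0.47 (camera adjusted p = 0.0527). Of 58 auxin genes, 9 rose and 4 fell, or 12 and 5 adjusted over the list alone, with IAA10 at 0.79 and ARF16 at 0.34 against PIN5 at -1.02 (camera adjusted p = 0.597).

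Sodium and potassium transport had 2 of 27 genes higher and 2 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.569). HAK23 and HAK25, potassium transporter genes, rose by 0.39 and 0.41, while AKT1 and HAK10 fell by 0.70 and 0.30. HAK10 did not pass without the 3 arrays between genotypes (adjusted p = 0.0673). Among 25 abscisic acid genes 4 rose and 1 fell, also adjusted over the list alone, and the degradation genes ABA8OX1 and ABA8OX2 rose by 0.72 and 0.49 (camera adjusted p = 0.812). Among 20 antioxidant genes 4 rose and none fell, or 6 and 1 adjusted over the list alone, with the peroxiredoxin gene PRXIIC at 0.45 and the superoxide dismutase gene sodCp at 0.38 (camera adjusted p = 0.497). Among 40 jasmonate genes 3 rose and 4 fell, or 3 and 5 adjusted over the list alone, with the allene oxide synthase gene AOS3 at -0.88 and the receptor gene COI1B at 0.31 (camera adjusted p = 0.0949). Of 6 WRKY genes, WRKY62 and WRKY76 fell by 1.07 and 1.26 (camera adjusted p = 0.119). Of 40 genes of phenylpropanoids, lignin and the Casparian strip, 5 rose and 3 fell, or 7 and 3 adjusted over the list alone, with OsCASPL2D1 at 0.91 and the alcohol dehydrogenase gene CAD6 at -0.85 (camera adjusted p = 0.986). Among markers of cells outside the root, 0 of 18 photosynthesis genes, 1 of 9 seed storage genes and 0 of 9 anther genes passed.

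Among named genes of FL478 roots, Pir7b fell by 3.70 (SE 0.43, adjusted p = 0.00056), OsPM19L1 by 3.37, the small heat shock protein gene HSP17.4 by 2.73, the laccase gene LAC24 by 2.50, the alternative oxidase gene AOX1a by 2.03 and AOS3 by 1.78. BURP10 rose by 3.12 (SE 0.49, adjusted p = 0.00467), BGLU16 by 1.81, EXP31 by 1.69, SS1 by 1.54, MADS57 by 1.46 and P5CS2 by 1.38. In FL478 the lists of jasmonate (40 genes), diterpenoid phytoalexin (16 genes), iron (25 genes), zinc, copper and manganese (26 genes), WRKY (6 genes) and ABC transporter (12 genes) genes were called as lower, with adjusted p from 0.000221 to 0.0367. None of the 6 calls held with an estimated correlation (adjusted p = 0.455 to 0.471 with an estimated correlation), and few members passed singly: 3 zinc, copper and manganese genes, 1 jasmonate gene and 1 iron gene fell. The jasmonate list was also called between replicate numbers over all genotypes, as lower in number 2 than in number 1 (adjusted p = 0.0402). That call too was lost with an estimated correlation (adjusted p = 0.687 with an estimated correlation). The iron list was called between numbers as given above. RAB16A rose by 1.28 (adjusted p = 0.0147) and SalT fell by 1.05 (adjusted p = 0.0375).

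In FL478, 303 probe sets were higher and 246 lower in salt. With replicate number as a block, fitted as an effect of each number shared by all genotypes, 897 were higher and 713 lower. AKT1 passed in that fit (adjusted p = 0.0327 against 0.177). Of 75 higher and 78 lower without the 3 arrays between genotypes, of which 1 is from IR29, 47 and 60 were shared. Leaving out control replicates 1 and 3 or salt replicates 1, 2 and 3 gave 53, 76, 190, 124 and 150 higher. Lower probe sets were 88, 97, 110 and 150 without control replicates 1 and 3 and salt replicates 2 and 3. Pir7b, OsPM19L1, AOS3, BURP10, BGLU16, SS1 and P5CS2 passed with any 1 array left out. HSP17.4, LAC24, AOX1a, EXP31, MADS57, RAB16A and SalT each lost the call without 2 to 5 of the 6 arrays. Without the 3 arrays between genotypes BURP10 (3.10, adjusted p = 0.0535) and P5CS2 (1.10, adjusted p = 0.0649) did not pass, and Pir7b, OsPM19L1, AOS3, BGLU16, SS1 and RAB16A did. In that fit the list calls of WRKY, zinc, copper and manganese, and ABC transporter genes were lost (adjusted p = 0.0763, 0.0607 and 0.0763). Leaving out control replicate 2 or salt replicate 3 singly gave 11 and 14 lists. The WRKY call was also lost without salt replicate 2 (adjusted p = 0.0634) and the ABC transporter call without 3 of the 6 arrays (adjusted p up to 0.107).

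IR29 roots, the sensitive genotype, raised BURP10 by 2.80 (SE 0.54, adjusted p = 0.03), SMR1 by 1.80, EXPB18 by 1.47, ITPK1 by 1.10, the phosphate transporter gene PT6 by 1.07 and OsCASPL2D1 by 0.99. PIN5 fell by 1.87 (SE 0.37, adjusted p = 0.0339), BZIP52 by 1.34, the adenylate kinase gene ADK-A by 0.90, the heme oxygenase gene HO1 by 0.82, HMA5 by 0.77 and GPI-B by 0.74. The lists of sugar transport and sucrose metabolism (adjusted p = 0.00782, and adjusted p = 0.0218 with an estimated correlation) and of iron uptake and storage (adjusted p = 0.019, and adjusted p = 0.932 with an estimated correlation) were called as lower. No member of either list passed singly, and 4 and 2 members fell when adjusted over the list alone. Without control replicate 2 and salt replicates 1, 2 and 3, 5, 1, 1 and 4 lists were called. The iron call was lost without 3 of the 5 arrays, with the highest adjusted p of 0.332 without control replicate 1. In IR29, 95 probe sets were higher and 101 lower, and without control replicate 1, which lies between genotypes, 7 were higher and 11 lower. Without all 3 such arrays 12 were higher and 12 lower, 8 and 7 of them shared. IR29 control has replicate numbers 1 and 2, and IR29 salt has numbers 1, 2 and 3. Salt is thus partly confounded with replicate number in IR29. With replicate number as a block, fitted as an effect of each number shared by all genotypes, 234 were higher and 223 lower in IR29. Without salt replicates 1, 2 and 3, 42, 160 and 52 were higher. Lower probe sets numbered 35 and 40 without salt replicates 1 and 3, and 159 without control replicate 2. All 12 named genes of IR29 except EXPB18 lost the call without control replicate 1, with adjusted p from 0.167 to 0.407, and EXPB18 lost it without control replicate 2 (adjusted p = 0.0615).

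In IR63731 roots, 17 probe sets were higher and 24 lower. SMR1 rose by 1.46 (SE 0.27, adjusted p = 0.0453) and OsCASPL2D1 by 0.84. OsNrx1-1, a nucleoredoxin gene, fell by 1.03, ADK-A by 0.84 and TPK2 by 0.58. Sugar transport and sucrose metabolism was the list called, as lower (adjusted p = 0.0395), and the call was lost with an estimated correlation (adjusted p = 0.0603 with an estimated correlation). None of its 41 genes passed singly. With replicate number as a block, fitted as an effect of each number shared by all genotypes, 106 probe sets were higher and 93 lower. Each of the 5 named genes lost the call without 4 to 6 of the 6 arrays, and the list lost it without 5 of them. Without the 3 arrays of other genotypes, which enter only through the spread, 24 were higher and 22 lower, and the list did not pass (adjusted p = 0.052). Leaving out control replicates 1 and 3 and salt replicates 1, 2 and 3 gave 3, 6, 6, 26 and 8 higher and 4, 5, 3, 11 and 7 lower.

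Among named genes of Pokkali roots, Nrat1, an aluminium transporter gene, rose by 1.12 (SE 0.18, adjusted p = 0.00919), MRS2-E, of a magnesium transporter family, by 1.02, OsC3H35 by 0.99, the auxin response gene IAA25 by 0.97, OsCASPL2D1 by 0.82 and the cytokinin-related histidine kinase gene HK4 by 0.73. HIRL2 fell by 2.14 (SE 0.37, adjusted p = 0.0138), OsNrx1-1 by 1.53, ILL3 by 1.45, LOL4 by 1.31, CRSH2 by 1.19 and BZIP52 by 1.06. The lists of jasmonate (adjusted p = 0.000117), sugar (adjusted p = 0.000189) and WRKY genes (adjusted p = 0.0331) were called as lower. With an estimated correlation the sugar call held (adjusted p = 0.00434 with an estimated correlation), and the jasmonate and WRKY calls did not (adjusted p = 0.768 with an estimated correlation for both). Between replicate numbers 1 and 2 the jasmonate list was also called, as lower in number 2 (median -0.21), but not with an estimated correlation (adjusted p = 0.687 with an estimated correlation). There the WRKY list had a median of -0.68 and did not pass (adjusted p = 0.0536). The WRKY call was lost without 4 of the 6 arrays, with adjusted p up to 0.126. Without control replicate 2 and salt replicate 2, 8 and 7 lists were called. In Pokkali, 92 probe sets were higher and 103 lower, and 75 and 95 without the 3 arrays of other genotypes. Array weights gave 324 and 311 in Pokkali, and replicate number as a block gave 515 and 416. With only the arrays compared, which leaves fewer degrees of freedom, 10 were higher and 16 lower in Pokkali, 16 and 42 in FL478, 0 and 0 in IR29 and 3 and 0 in IR63731. Nrat1, OsNrx1-1 and CRSH2 passed with any 1 array left out, and the other 9 named genes lost the call without 2 to 6 of the 6 arrays. Leaving out control replicates 1 and 3 and salt replicates 1, 2 and 3 gave 25, 28, 51, 32 and 54 higher and 44, 34, 46, 63 and 32 lower.

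The genotypes shared much of the direction of their response. BURP10 had estimates from 1.45 to 3.12 over the 4 genotypes, and 8 probe sets were called as higher and 10 as lower in each genotype. Of the probe sets called in the mean of the other 3 genotypes, 2087 of 2244 had the same direction in FL478, 3188 of 3385 in IR29, 2481 of 2613 in IR63731 and 2370 of 2632 in Pokkali, against 60.1% to 63% of the probe sets not called. These counts used all arrays. As 3 arrays of FL478 and IR29 lie towards IR63731, the effects of these genotypes may not be independent. Across probe sets, which are not independent replicates, the salt effects of pairs of genotypes correlated with Pearson's r from 0.33 (IR63731 and Pokkali) to 0.51 (IR29 and IR63731) and Spearman's rho from 0.31 to 0.40. Jackknife standard errors of r over arrays ran from 0.12 to 0.24, so the order of the 6 pairs was not resolved. Without the 3 arrays between genotypes r ran from 0.167 (IR29 and Pokkali) to 0.402 (FL478 and IR29). Leaving out 1 array took r to 0.167 for IR29 and Pokkali (without IR29 control replicate 1), 0.167 for IR63731 and Pokkali and 0.224 for FL478 and IR63731 (both without IR63731 salt replicate 2), and 0.2499 for FL478 and IR29 (without IR29 salt replicate 2).

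Differences in salt response between genotypes passed the test at few probe sets. A probe set of the gene LOC4335593, which has no name in the annotation, was at 5.52 ± 0.51 (SD, n = 3) in FL478 control roots and 3.13 ± 0.24 (SD, n = 3) in FL478 salt roots. In control roots it was at 3.26 in IR29 and 3.43 in Pokkali, within the 2.70 to 4.26 of 23 control probe sets for sequences outside rice, so a fall could not be measured there. The value in FL478 salt roots is in the same range, so the size of the fall in FL478 is not exact. The tests of the difference passed (adjusted p = 0.00557 against IR29 and 0.0198 against Pokkali), but the difference rests on the level in FL478 control roots. A second probe set of BGLU16, which is not the one named above, was at 2.90 in control and 4.31 in salt roots of FL478 and at 2.69 and 2.82 in Pokkali (adjusted p = 0.0198 for the difference in response). Of these, the values from 2.69 to 2.90 are at background, so the size of the difference is not exact. A probe set with no gene in the annotation had effects of -2.18 in FL478 and -0.42 in Pokkali (difference -1.76, SE 0.25, adjusted p = 0.0198). It was at 6.55 in FL478 and 4.81 in Pokkali control roots, and at 4.37 and 4.39 in their salt roots. The salt values lie just above the 4.26 of the background range, so little room was left for a fall in Pokkali. These items were chosen after their values were seen, because the rule for named genes gave none.

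With limma, 1 probe set differed in response between FL478 and IR29, 3 between FL478 and Pokkali, and 0 between IR63731 and IR29, Pokkali and IR29, or the mean of the 3 tolerant genotypes and IR29. At an unadjusted p under 0.05 these 5 comparisons gave 2628, 3009, 1755, 2481 and 2123 probe sets, where chance gives 2859.7. All but that of FL478 and Pokkali lie below chance, so these tests may be conservative. The simulated data held no difference in response, so the power to find one was not assessed. Few calls therefore do not show that the genotypes respond alike. In comparisons with IR29, whose control has no replicate number 3, number is also partly confounded. No gene list was called by camera between the tolerant genotypes and IR29. Without the 3 arrays between genotypes the 5 counts were 2, 3, 2, 3 and 4, with 4 lists called between the tolerant genotypes and IR29, where IR29 then had 1 control array. Without IR29 control replicate 1, IR29 salt replicates 1 and 2, Pokkali control replicate 1 and Pokkali salt replicate 1 singly, 4, 2, 1, 1 and 1 lists were called there. Without IR29 control replicate 2, so that the array between genotypes alone stood for IR29 control, 65, 60, 55 and 85 probe sets differed from IR29 in FL478, IR63731, Pokkali and the tolerant mean. Without IR29 salt replicate 2, 39 differed in Pokkali and 23 in the tolerant mean. Without any 1 other array these 4 counts lay between 0 and 7. Without FL478 control replicate 2 or Pokkali control replicate 3, no probe set differed between FL478 and Pokkali, and without Pokkali salt replicate 3, 11 did. Without FL478 salt replicates 1 and 2, Pokkali control replicate 2 and Pokkali salt replicates 1 and 2 in turn, 7, 5, 5, 5 and 7 did.

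Control roots of the genotypes differed at many named genes. OsCASPL1D1, of a family of Casparian strip membrane protein-like genes, differed from IR29 on the log2 scale by -3.75 in FL478, -5.10 in IR63731 and -5.57 in Pokkali (adjusted p = 0.000343, 9.2e-06 and 9.42e-07). OsPP2C12, a protein phosphatase gene, differed from IR29 by -4.08 in IR63731 and by -4.08 in Pokkali, and was 4.03 higher in FL478 than in Pokkali. ILL3 was higher than in IR29 by 4.24 in FL478 and 3.74 in Pokkali, and SPO11-4 by 2.71 and 2.92. HIRL2 was higher than in IR29 by 2.33 in FL478 and 3.25 in Pokkali. The iron-regulated transporter gene IRT2 (4.33, SE 0.98, adjusted p = 0.0282) and PSK4 (2.46) were higher in FL478 than in IR29, and OsICS (-2.05), mads47 (-1.84), BGLU33 (-1.64) and PRIN2 (-1.13) were lower. In IR63731, APX5 (2.17), PLA2-III (0.95), ABA8OX2 (0.89) and MSRB3 (0.88) were higher than in IR29, and the aldehyde oxidase gene AO-1 (-2.66), BC1L9 (-2.19) and CCS1 (-2.17) were lower. In Pokkali, the small heat shock protein gene HSP18.1 (3.68) and the chalcone synthase gene CHS1 (2.52) were higher than in IR29, and the zinc and cadmium transporter gene HMA2 (-3.93), BURP2 (-3.15) and CBP1 (-2.95) were lower. Against Pokkali, FL478 had higher BURP2 (5.31), HMA2 (3.30), OsPP2C16 (2.73) and PSK4 (2.70) and lower HSP18.1 (-3.92), OC-XII (-3.12), PIK6-NP (-3.11), mads47 (-2.51) and CML32 (-1.99).

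In control roots, 382 probe sets were higher and 406 lower in FL478 than in IR29, 150 and 361 in IR63731, and 1198 and 1175 in Pokkali, and 1230 were higher and 1266 lower in FL478 than in Pokkali. A probe set can read a sequence difference between genotypes as a difference in level, and the arrays cannot separate these. Without the 3 arrays between genotypes, 425 were higher and 453 lower, 500 and 513, 918 and 917, and 974 and 967 in the same order, so the excess of lower probe sets in IR63731 was not kept. Without IR29 control replicate 2 they were 289, 149 and 1064 for the 3 comparisons with IR29. IR63731 against IR29 gave 865 without IR29 control replicate 1, 315 without IR63731 control replicate 1 and 326 without IR63731 control replicate 2, and Pokkali against IR29 gave 1490 without Pokkali control replicate 3. IRT2 lost its call without any 1 of the FL478 control arrays and without IR29 control replicate 2, and had 7.54 (adjusted p = 3.29e-09) without the 3 arrays between genotypes. BURP2 between Pokkali and IR29 lost it without IR29 control replicate 1 (adjusted p = 0.266). Leaving out IR29 control replicate 2 ended the calls against IR29 of PSK4, HIRL2, mads47 and PRIN2 in FL478, of APX5, PLA2-III, ABA8OX2, MSRB3, BC1L9 and CCS1 in IR63731 and of CHS1 in Pokkali, with adjusted p from 0.0738 to 0.824.

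At probe sets that set its parents apart, FL478 was nearer IR29 at some and nearer Pokkali at others. Of 467 probe sets that differed by at least 2 log2 units between IR29 and Pokkali over both treatments, 194 (41.5%, SD 4.18 between FL478 arrays) were nearer Pokkali in FL478. On the scale from IR29 at 0 to Pokkali at 1, 45.6% stood below 0.25 and 31.5% above 0.75. IR63731, which is not stated to be of this cross, had 47.5% nearer Pokkali, 44.5% below 0.25 and 34.0% above 0.75. Among 238 genes with such a probe set, neighbours along a chromosome had the same nearer parent in 149 of 226 pairs, against a mean of 116.4 over 10000 shuffles (permutation p = 1e-04, one-sided, the smallest they can give). IR63731, set on the same scale, gave 146 of 226 pairs against 112.7, so neither the positions nor this count sets FL478 apart from IR63731.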

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

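The tests of mixed samples, mislabelled arrays, a response to treatment, the weight of the 3 arrays and RNA quality under salt, and the splits with the shared salt effect removed, were chosen after the result was seen.

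The salt response differed between genotypes, by a test of the difference, at 3 probe sets. That of LOC4335593 differed by -2.47 between FL478 and IR29 and by -2.10 between FL478 and Pokkali. In IR29 and Pokkali it was at background in both treatments, so a fall could not be measured there. FL478 salt roots were at background too, so both values rest on the level in FL478 control roots and are not exact sizes. That of BGLU16 differed by 1.29 between FL478 and Pokkali, and by 1.40 without the 3 arrays between genotypes, where it did not pass (adjusted p = 0.0658). It was at background in Pokkali and in FL478 control roots, so its size is not exact. In the fit without the 3 arrays another probe set of BGLU16 passed for that difference (2.201, adjusted p = 0.0164), against 1.77 (adjusted p = 0.125) with all arrays. That with no gene in the annotation differed by -1.76 between FL478 and Pokkali. Its salt roots stood just above background in both (4.37 and 4.39), and its control roots at 6.55 and 4.81. This difference therefore also rests on the level in FL478 control roots. Among 100 drawn splits of the arrays within FL478 and Pokkali, 14 gave at least as many differing probe sets as the real 3, with 239 in the highest other. Such splits can exchange control and salt in 1 genotype, which turns the shared salt effect into a difference, so they do not measure chance for this count. With the shared effect removed, 3 of the 80 splits that part every pair of FL478, and 2 of the 32 that part every pair of both, gave at least 3, with 6 in the highest other. These shares lie on both sides of 0.05, so whether chance gives this count stays open.

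FL478 salt replicate 2, IR29 control replicate 1 and FL478 control replicate 3 lay between their genotype and IR63731 at probe sets that set genotypes apart. An unmixed array under a wrong label is argued against by the highest position at another genotype's probe sets, 0.598. That position is of FL478 salt replicate 2, whose nearest array was IR63731 salt replicate 2. A sample that is mostly IR63731 under a wrong label is therefore not excluded there. A response to treatment is argued against by the other arrays of the same groups, which reached 0.0392 towards IR63731. A mixed sample may be the source: the share of IR63731 signal was at least 0.121 in each of the 3 by both measures. By probe sets higher in IR63731 the shares were 64.8%, 42.9% and 12.1%, against at most 1.21% in the other 8 arrays of FL478 and IR29. By probe sets lower in IR63731 they were 70.7%, 55.6% and 19.8%, against at most 19.4%, so for FL478 control replicate 3 this measure barely separates, and whether plants, seed or RNA were mixed was not tested.

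Arrays with the same replicate number deviated together. A difference in RNA quality is argued against by the control probe sets, whose 3 prime minus 5 prime values differed by at most 0.0274 between numbers (permutation p = 0.838). A different time of day at harvest could not be told apart from other causes: of the genes set beforehand, PRR1 changed by -1.49 from number 2 to 3 (adjusted p = 9.21e-05) and PRR95 by -0.39 (0.385 in size, adjusted p = 0.538). A growth batch behind the numbers was not tested.

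The salt response in the mean of 4 genotypes was set against the same explanations. That the 3 arrays between genotypes made all of it is argued against by the other 20 arrays: their real split gave 2703 probe sets and was 1 of 100 drawn splits with as many, with 105 in the highest other. The other splits keep the salt effect in their spread, which lowers their counts, so 105 is not a count of false calls. Of the 4753 probe sets, 2374 (49.9%) were still called without the 3 arrays, and whether the rest ended through fewer arrays was not tested. Time of day as the level of 4 clock genes measures it, as the whole cause, is argued against by the fit with that level as a covariate. In it, 63.8% of the 4753 probe sets were still called. Effects of time of day that do not follow that level would remain among these calls. A part through time of day cannot be told apart from salt: 0 of 7 clock genes passed, yet the salt effects correlated with the change from number 2 to 3 across probe sets (r = -0.294), and with the replicate block CCA1, PRR1 and PCL1 passed (adjusted p = 0.000109, 0.00138 and 0.00143). The mean 3 prime minus 5 prime value of 4 probe pairs was higher in salt by 0.0843 (permutation p = 0.0194), mostly through actin and Gapdh, while cyclophilin was slightly lower. RNA quality as these pairs measure it, as the whole cause, is argued against by the fit with that value as a covariate: the real split gave 1807 probe sets and was 1 of 100 drawn splits with as many, with 225 in the highest other. Here too the spread lowers the counts of the other splits, so 225 is not a count of false calls. Effects of RNA quality that do not follow that value would remain among the 1807. A part through RNA quality cannot be told apart from salt: 37.1% of the 4753 probe sets were still called with the covariate, and all kept their direction. The median size of their effects went from 0.346 to 0.317 and the median SE from 0.0783 to 0.0896. How far each of these ended calls was not tested. A response to salt itself stays open as the biological explanation.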

How the results depend on the processing

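The fits without the 3 arrays between genotypes and with a covariate were chosen after the result was seen. Named genes, 243 results, kept their direction and side of the threshold in 238 with the replicate block, 232 of 232 measured with only probe sets above the median, 234 with array weights, 229 with trend and robust, 225 with quantile normalization again, 208 of 208 without _s_at and _x_at probe sets, 194 with only the arrays compared and 173 without the 3 arrays. Where a value below differs, the cause was not tested, except that fits with fewer arrays have fewer degrees of freedom. Low signal limits probe sets near the background, which the filter at the median leaves out.

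With the replicate block, probe sets higher and lower in salt were 897 and 713 in FL478, 234 and 223 in IR29, 106 and 93 in IR63731, 515 and 416 in Pokkali, and 4195 and 2919 in the mean of 4 genotypes, and 5 differed in response between FL478 and Pokkali. In IR29 and Pokkali the numbers did not pair the arrays (correlations -0.179 and 0.119, and -0.066, -0.0156 and 0.316). The 2 control arrays of IR29 deviate from their mean as mirror images, and control replicate 1 lies between genotypes. Pairing is therefore poorly measured in IR29. The block ended no call of a named gene or gene list. HKT1;5 in IR29 reversed to -0.35 with the block and -0.013 with quantile normalization again, and passed in neither.

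With only probe sets above the median, 500 were higher in FL478, and 0 differed in response between FL478 and IR29 and 1 between FL478 and Pokkali. Between the tolerant mean and IR29, 3 differed with trend and robust, 3 with quantile normalization again and 3 without _s_at and _x_at probe sets. With array weights, 104 were higher and 91 lower in IR63731, 324 and 311 in Pokkali, and 1, 10, 5 and 5 differed in response for IR63731 and IR29, Pokkali and IR29, FL478 and Pokkali, and the tolerant mean and IR29. With only the arrays compared, 16 were higher and 42 lower in FL478, 0 and 0 in IR29, 3 and 0 in IR63731, 10 and 16 in Pokkali. In that fit 0 differed in response between FL478 and IR29 and 0 between FL478 and Pokkali, and control plants of FL478, IR63731 and Pokkali differed from IR29 at 239, 198 and 1311. With an estimated correlation 0, 1, 0, 1 and 1 lists were called in FL478, IR29, IR63731, Pokkali and the mean.

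Without the 3 arrays, 75 were higher and 78 lower in FL478, 12 and 12 in IR29, 1652 and 1051 in the mean, and 2, 2, 3 and 4 differed in response from IR29 in FL478, IR63731, Pokkali and the tolerant mean. Control plants of IR63731 and IR29 differed at 1013. Lists called were 3 in FL478, 4 in IR29, 0 in IR63731 and 4 for the tolerant mean against IR29. P5CS1 reversed to -0.035 in the mean and -0.070 in IR29, and DHN1 to 0.14 in FL478, none of them past the threshold.

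With the level of 4 clock genes as a covariate, 109 named gene results of the mean kept direction and side of the threshold, 20 lost the call, 1 gained it and P5CS1 reversed to -0.0077 without passing. With the 3 prime minus 5 prime value as a covariate, 1006 probe sets were higher and 801 lower in the mean, 82 named gene results kept direction and side, 48 lost the call and LEA3 reversed to -0.022 without passing.

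Leaving out 1 array, where a group left with 1 array is assumed to vary like the others, gave from 53 to 371 higher and 88 to 274 lower in FL478, 7 to 160 and 11 to 159 in IR29, 3 to 26 and 3 to 24 in IR63731, 25 to 89 and 32 to 92 in Pokkali, and 1942 to 3090 and 1315 to 2026 in the mean. Responses differed at 1 to 65 (FL478 and IR29), 0 to 60 (IR63731 and IR29), 0 to 55 (Pokkali and IR29), 0 to 11 (FL478 and Pokkali) and 0 to 85 (tolerant mean and IR29). Control plants differed at 289 to 778, 149 to 865 and 1064 to 2437 for FL478, IR63731 and Pokkali against IR29, and at 1685 to 2117 for FL478 against Pokkali. Lists numbered 5 to 14 in FL478, 1 to 5 in IR29, 0 to 1 in IR63731, 2 to 8 in Pokkali, 2 to 5 in the mean and 0 to 4 for the tolerant mean against IR29. Results whose sign turned when 1 array was left out ranged, for P5CS1, from -0.0075 to 0.064 in the mean, -0.15 to 0.14 in FL478, -0.085 to 0.13 in IR29, -0.068 to 0.056 in IR63731 and -0.011 to 0.21 in Pokkali. In FL478 LEA3 ranged from -0.18 to 0.075 and DHN1 from -0.22 to 0.14, and in IR29 HKT1;5 from -0.96 to 0.99 and DHN1 from -0.43 to 0.65. None of these passed in any of those fits.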

Other observations

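No test reported in this part was chosen after its result was seen. In further gene groups some members passed in the mean of 4 genotypes, and no list was called by camera. Of 27 beta-glucosidase genes 5 rose and 4 fell, with BGLU16 at 0.86 and BGLU34 at -0.83 (camera adjusted p = 0.822). Of 31 cytokinin genes 4 rose and 3 fell, with the response regulator gene RR1 at 0.77 and LOGL1, of a cytokinin-activating family, at -0.70 (camera adjusted p = 0.782). Of 47 homeobox genes 7 rose and 0 fell, with HOX1 at 0.55 (camera adjusted p = 0.706). Of 31 CIPK and CBL calcium sensor genes 3 rose and 6 fell, with CIPK17 at -0.85 (camera adjusted p = 0.292). Of 45 genes of secondary wall and cellulose 7 rose and 1 fell, with CESA3 at 0.23 (camera adjusted p = 0.945).

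Other splits of the arrays were counted for each model result with at least 3 arrays per group. The mean of 4 genotypes gave 4753 probe sets, more than any other of 100 drawn splits. It was thus 1 of 100, with 151 in the highest other, and chance as the whole cause is argued against. The other splits keep the salt effect in their spread, which lowers their counts, so 151 is not a count of false calls. For gene lists in that mean, 74 of 100 splits gave at least the real 2, with 14 in the highest other, so chance is not excluded. Why some splits gave several times the real count was not tested. In single genotypes the 10 splits are too few for a share under 0.05. The real split was 1 of 10 with as many probe sets in FL478 (549, highest other 10), IR63731 (41, highest other 0), Pokkali (195, highest other 7) and control FL478 against Pokkali (2496, highest other 0). For gene lists, 4 of 10 splits gave as many in FL478 (real 6, highest other 12), 9 of 10 in IR63731 (real 1, highest other 9) and 6 of 10 in Pokkali (real 3, highest other 12). Among the 4 splits that part all pairs, the highest other was 10 in FL478 and 0 in IR63731.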
